A study of Mus musculus with 7 samples.

How the data were processed

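The series holds 7 samples of mouse bone marrow cells sorted as live, lineage-negative, Kit-positive and Sca1-positive (LSK) cells, the fraction that contains blood stem cells and multipotent progenitors. By the genotype labels 4 samples came from mice with a loxP-flanked Csnk1a1 gene and the Mx1Cre transgene (called floxed here), and 3 from mice with Mx1Cre alone. Mx1Cre is a recombinase driven by an interferon-inducible promoter and is used to delete loxP-flanked DNA in blood cells. Count matrices of 2 floxed libraries and 1 control library were used, and the other 4 samples were not analysed here. Replicate numbers only name the libraries. Nothing in the labels says that the libraries came from separate animals. The p-values therefore rest on the spread between these libraries, pooled over genes, which may be technical. The genotype label reads fl/fl while the series title speaks of haploinsufficiency, and the labels do not say which part of the gene is deleted, so a 3' tag of Csnk1a1 may lie outside it and then checks nothing.

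The deposited values are raw UMI counts per gene and droplet barcode, with all 737280 barcodes present in each library. Libraries were made with a 10x Chromium 3' v2 kit, per the labels' protocols. Cell Ranger 2.1.1, Seurat 3.1.0 and the mm10 build are named in the submitters' processing notes without their roles. The annotation and any filters the authors applied are not given in the sources used here. Of 27998 gene identifiers, 27722 matched the GENCODE M21 annotation (GRCm38), which gave chromosomes and positions.

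Cells were called per library as barcodes above 10% of the 99th percentile of the 3000 largest barcodes, which gave minimums of 2016, 1759 and 1730 UMIs in floxed library 1, floxed library 2 and the control. Cells with over 10% mitochondrial UMIs or under 500 genes were removed. Scrublet's automatic threshold marked 1, 0 and 2 cells and so had not worked. The cells with the highest doublet scores were removed in its place, at 0.8% per 1000 cells, which took out 69, 691 and 279 cells. That rule was chosen after the automatic result was seen.

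Cells were clustered with scanpy 1.11.5 on 30 principal components of 2000 variable genes, of which 1994 remained without Csnk1a1, mitochondrial genes and sex-linked genes, with 20 neighbours and Leiden resolution 1.0, without integration. This gave 16 clusters. An earlier clustering with approximate neighbours had been looked at and was replaced by exact neighbours so that repeats give the same clusters. A cluster was named "X-like" when at least 3 markers fixed before the data were examined were among its top 25 genes by fold, and more than of any other class. Clusters with at least 3 markers of mature cells there, and more than of progenitors, were set apart as mature, and the others are called progenitor clusters. Both naming rules were written after the cluster tables were seen. 8 clusters were named, 8 stayed unnamed, and 5 were mature.

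UMI counts of all kept cells, or of the cells of a class with at least 50 cells in every library, were summed per library and tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test, R 4.3.3). Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and a gene that passes is said to be called. With 2 floxed libraries and 1 control there was 1 residual degree of freedom. The spread came from the floxed libraries, and the lone control was assumed to vary like them. Each gene's spread was drawn toward the trend over all genes, so a call does not show that the floxed libraries agreed. Prg2, for example, was called although the floxed libraries lay 6.41 log2 units apart. Fold changes are floxed minus control, levels are TMM-scaled CPM unless said to be of all UMIs, and differences of single libraries are on the log2(CPM + 0.5) scale. A gene without counts in the control is given as a lower bound against a floor of 3 counts in that library. Gene lists fixed before the data were examined (37 with at least 4 tested members) were tested with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation and with fry. With 1 residual degree of freedom those further tests could hardly be passed. Even the list of sex-linked genes, with all 6 members called, did not pass them. A description without a test counted genes with at least 50 counts that differed from the control by at least 1.5-fold the same way in both floxed libraries, with the smaller log2 difference beyond the gap between those libraries (the size rule). Shares of cells and cell cycle phases were compared by two-sided exact permutation tests over libraries, where 3 splits exist and the smallest possible p is 0.333. Binomial intervals are exact (Clopper-Pearson) and Poisson intervals exact, both at 95%, and cover counting error only. Phases and genes per cell were taken after thinning every cell to 2000 UMIs, leaving out 0, 99 and 115 shallower cells.

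The text names Csnk1a1, the up to 14 higher and 14 lower genes of largest change among called genes at a mean of at least 20 CPM that move the same way in both floxed libraries, up to 4 called members per list or otherwise the 2 most abundant, and up to 5 higher and 5 lower genes per class by the same rule. Since 8 genes passed the rule for all cells, fewer than 10, genes among the 10 higher and 10 lower by the size rule were added as values. Other genes named were chosen after their values were seen. The edgeR step was tested on simulated counts with the means and library sizes of the all-cell comparison (13325 genes, 3 runs, 200 changed genes per run). Its common dispersion was used for every gene. It called 3.67% of genes changed 2-fold, 53.3% of genes changed 4-fold and 0.033% of unchanged genes. The floxed libraries were not copies of each other, with a chi-square per degree of freedom of 81.7 over 12804 genes.

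Alternatives fixed before the data were examined were other scalings (median of ratios, library totals), DESeq2 1.42.0 and limma-voom, other filters on genes, a minimum of 1000 UMIs, a 5% mitochondrial limit, doublets kept, equal cluster shares, sex-linked genes left out, a least fold of 1.2, thinned totals, other clustering resolutions and each floxed library left out. Progenitor clusters only, genes outside X and Y only, both together and a robust fit were added after seeing the data. Transcripts of Xist and its antisense gene Tsix overlap, and strand handling in the authors' counting is not given in the sources used here, so Tsix is uncertain. Genes with close copies or pseudogenes (Rpl39l, Rpl10l, Rpl7a-ps3, Xlr, Xlr3a, the haemoglobin genes and Bcl2a1b) are uncertain too, since counts can be split or shared between copies.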

Results

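The stem cell compartment of mice with a floxed Csnk1a1 gene was profiled by single-cell 3' RNA sequencing of sorted LSK bone marrow cells and set against cells of mice with Mx1Cre alone. Floxed library 1 held 28339636 UMIs, floxed library 2 held 58973119 and the control library held 45076625. After filtering, 2861, 8603 and 5629 cells were kept, with medians of 6187, 5040 and 5366 UMIs and of 1917, 1599 and 1629 genes per cell. Cells called held 75.3%, 91.9% and 81.3% of each library's UMIs. The kept cells fell into 16 clusters. Clusters were led by markers of blood stem cells (HSC-like), lymphoid progenitors, granulocyte-monocyte progenitors, dendritic cells, T, NK or innate lymphoid cells and neutrophils, and 8 stayed unnamed.

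The targeted gene was compared between genotypes. Csnk1a1, which encodes casein kinase 1 alpha, a kinase of the complex that marks beta-catenin for destruction, was lower in both floxed libraries than in the control. Its level was 132 CPM of all UMIs in floxed library 1 (95% Poisson interval 127 to 137), 111 in floxed library 2 (108 to 114) and 157 in the control (153 to 162). The gene (ENSMUSG00000024576) lies on chromosome 18 at 61555274 to 61590061 on the plus strand. Csnk1a1 was lower than in the control in both floxed libraries in 13 of the 16 clusters. In HSC-like cells it was at 143 CPM of all UMIs in floxed library 1, 104 in floxed library 2 and 142 in the control. The fitted log2 fold change of Csnk1a1 was -0.46 with a standard error of 0.36 and did not pass the test (edgeR adjusted p = 0.99994). Of 1295 genes of similar abundance, within 2-fold, 4 (0.309%) were at least as low in both floxed libraries, and 5 were as high by that size. Csnk1e, the other abundant member of the casein kinase 1 list, was at 38.0 and 40.9 CPM against 42.2 in the control, and no member of that list was called.

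**Figure D1:**
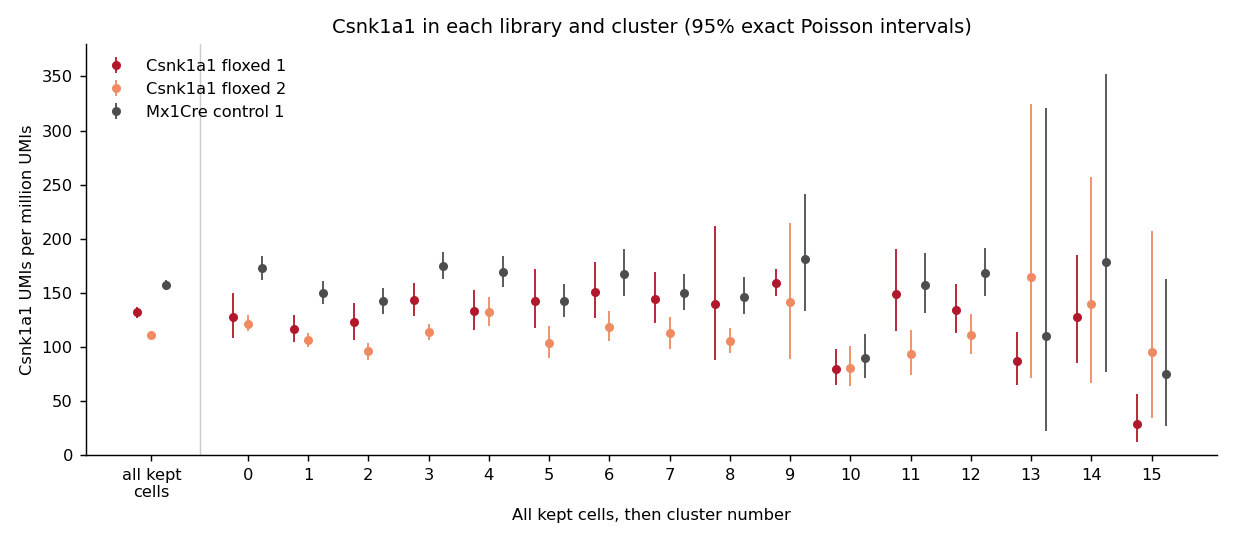
Csnk1a1 level as CPM of all UMIs in all kept cells and in each of the 16 clusters, for both floxed libraries and the control, with 95% exact Poisson intervals. Over all kept cells the floxed libraries stand at 132 and 111 and the control at 157, and in 13 clusters both floxed points lie below the control.

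Across all kept cells the genes that differed most were genes of the sex chromosomes and genes of mature blood cells. Xist, the RNA that silences an X chromosome in female cells, was at 1.70 and 0.961 CPM in the floxed libraries and 3847 in the control. The Y-linked genes Eif2s3y, a translation factor subunit, and Ddx3y, an RNA helicase, were at 48.2 and 37.8 CPM and at 39.1 and 30.4 CPM in the floxed libraries and had no counts in the control, at least 472-fold and at least 381-fold higher. Each comparison of floxed and control libraries here is therefore also a comparison of libraries that differ in Xist and Y-linked RNA. Jchain, which joins the units of secreted IgM and IgA, rose to 2107 CPM in floxed library 1 and stood at 29.3 in floxed library 2 and 4.59 in the control. The eosinophil granule gene Prg2 was at 120, 0.917 and 0.182 CPM in the same order, and Ly6d, a surface marker of early B-lineage and some dendritic cells, at 110, 5.17 and 3.40 CPM. The basophil protease genes Prss34 (104, 11.97 and 7.41 CPM) and Mcpt8 (93.7, 29.2 and 15.4 CPM) were called higher as well.

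In the edgeR test 72 of 13325 genes were called, 59 higher and 13 lower in the floxed libraries, and 271 had an unadjusted p under 0.05. Of the calls 6 lay on X and 4 on Y, more than their share of the tested genes (Fisher's exact test, p = 0.000115). Both floxed libraries moved the same way in 48 of the 72, and in 20 both differed from the control by more than from each other. In 47 calls floxed library 1 stood apart from both other libraries and in 5 floxed library 2 did. With the 5 mature clusters left out 40 genes were called, 25 higher and 15 lower, of which 33 were among the 72. DESeq2 called 10 genes, and library totals in place of TMM gave 13 calls, 8 higher and 5 lower. Without either floxed library no residual degree of freedom remained, so no call could be tested without floxed library 1.

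**Figure D2:**
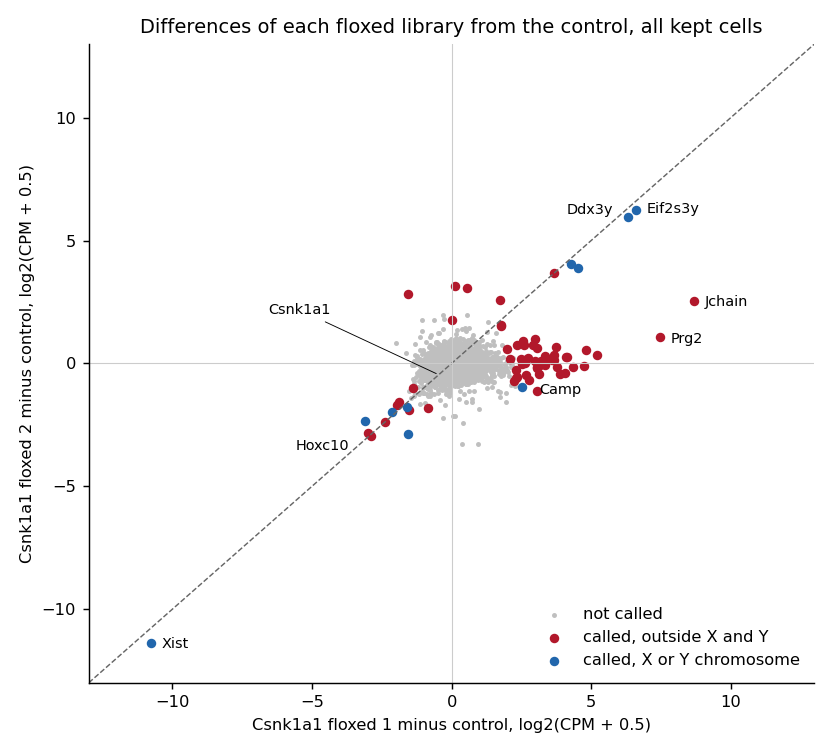
Difference of floxed library 1 (x axis) and floxed library 2 (y axis) from the control for each tested gene, as log2(CPM + 0.5), with called genes in red (outside X and Y) and blue (X or Y) and the dashed line marking equal differences. Most of the red points lie far to the right at small vertical values, while Xist, Ddx3y and Eif2s3y lie along the dashed line. Those red points belong to the 47 calls in which floxed library 1 stood apart, which also hold Cybb on X, a blue point.

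A set of 9 lists, 7 of markers of mature and stromal cells and 2 of lineage programmes, passed in all kept cells, with larger medians in floxed library 1 than in floxed library 2. Their adjusted p by camera lay between 2.9e-29 for mast cells and 0.016 for B cells, and none passed with an estimated correlation (adjusted p = 0.823 for 7 lists and adjusted p = 0.824 for neutrophils and B cells). Of 10 tested mast cell, basophil and eosinophil markers 4 rose (7 adjusted over the list alone), among them Prg2 and Epx, the eosinophil peroxidase gene at 4.38 CPM in floxed library 1 and without counts in the other 2 libraries. Of 12 neutrophil markers 2 rose (9 adjusted over the list alone), the chitinase-like gene Chil3 (52.4, 2.42 and 5.92 CPM) and Camp, which encodes an antimicrobial peptide (711, 65.8 and 105 CPM). Of 22 genes of the granulocyte-monocyte programme 3 rose (5 adjusted over the list alone), the granule genes Fcnb and Elane and their regulator Cebpe, with Elane at 146, 19.1 and 29.3 CPM, Fcnb at 15.8, 0.218 and 0.304, and Cebpe at 13.8, 1.40 and 2.31. Among 12 macrophage and monocyte markers 1, Ly6c2, rose (4 adjusted over the list alone), at 119, 7.49 and 8.35 CPM. Of 9 B cell markers 2 rose (2 adjusted over the list alone), the B cell receptor subunit gene Cd79a (31.9, 2.88 and 3.07 CPM) and Ms4a1, which encodes CD20 (3.04, 0.502 and 0.0911 CPM). The T and NK cell list (9 tested) had 1 call, the granzyme gene Gzma at 2.19, 0.393 and 0.0304 CPM, the dendritic list (11 tested) had 1, Ly6d, and the lymphoid programme (21 tested) had 1, Jchain, with the same numbers adjusted over the list alone. Of 9 stromal and endothelial markers 2 rose (3 adjusted over the list alone), the chemokine gene Cxcl12 at 13.2, 0.961 and 1.12 CPM and the matrix gene Mgp at 4.38, 0.721 and 0.121. Jchain, Ly6c2, Ly6d, Cd79a, Prg2 and Cxcl12 belong to different lists but were all among the top genes of the unnamed cluster 13. Prg2 was also a top gene of cluster 11 and Ly6d of cluster 4. Calls in several lists therefore need not mark several cell types.

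Of these 9 lists 5 had medians that turned with the library. In floxed library 2 the median log2 difference from the control was -1.14 for neutrophil, -0.28 for B cell, -0.20 for dendritic, -0.19 for lymphoid and -0.04 for T and NK genes, where floxed library 1 gave 1.83, 0.52, 0.81, 0.35 and 1.197. The other 4 stayed above 0 in floxed library 2, at 0.51 for mast cell, basophil and eosinophil genes (6 of 10 higher in both libraries), 0.10 for stromal, 0.018 for macrophage and 0.0073 for granulocyte-monocyte genes, against 1.13, 0.77, 1.04 and 0.28 in floxed library 1. The erythroid list (6 tested) did not pass (adjusted p = 0.50 by camera) and ran the other way, at -0.43 in floxed library 1 and 0.57 in floxed library 2, with 0 called members (2 adjusted over the list alone). With equal cluster shares in every library the neutrophil list was called lower (adjusted p = 4.3e-07 by camera) and the T and NK list lost its call (adjusted p = 0.81). In the progenitor clusters the neutrophil (adjusted p = 0.00027), macrophage (0.00028) and granulocyte-monocyte lists (0.00075) passed as higher, with neutrophil medians of 0.87 and -0.38. The erythroid list passed there as lower (adjusted p = 0.0046 by camera), with medians of -1.77 in floxed library 1 and 0.79 in floxed library 2. The mast cell list (adjusted p = 0.0505, medians 0.012 and 0.35), the stromal list (0.20, medians -0.37 and -0.25) and the T and NK (0.43), B cell (0.62), dendritic (0.74) and lymphoid lists (0.97) did not pass there. Mature clusters held 13.6% of kept cells in floxed library 1 (binomial interval 12.4 to 14.9), 4.37% in floxed library 2 (3.95 to 4.82) and 6.20% in the control (5.58 to 6.86). These shares include cluster 11, whose top genes mixed mast cell, basophil and eosinophil markers with markers of megakaryocyte-erythroid progenitors. The neutrophil result at equal cluster shares leans on a small cluster. Cluster 15, the neutrophil-like one, held 276586 UMIs in floxed library 1, 63138 in floxed library 2 and 80149 in the control. The correlation estimated for the neutrophil list was 1, where camera was preset to 0.01.

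Cell cycle and histone genes were higher in both floxed libraries as lists, without a called member. Median log2 differences of the 53 G2M genes were 0.21 and 0.24 in floxed libraries 1 and 2, those of the 41 S phase genes 0.17 and 0.19, and those of the 62 histone genes 0.24 and 0.18, with 41, 27 and 38 members higher in both. Camera gave adjusted p = 7.8e-06, 0.0024 and 0.00042, and adjusted p = 0.823 for each with an estimated correlation. With equal cluster shares the G2M and S phase lists still passed (adjusted p = 0.0018 and 2.7e-06) and the histone list did not (adjusted p = 0.18). None of their members passed adjusted over the list alone. The most abundant members went both ways, with Hmgb2, a chromatin protein gene, at 1178 and 1547 CPM against 1240, Cks2 at 302 and 423 against 321, Rfc2 at 212 and 277 against 254, Cdca7 at 121 and 164 against 135, Hist1h2ap at 168 and 364 against 352 and Hist1h1c at 73.2 and 91.6 against 88.6 in the control.

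The type I interferon response and cholesterol synthesis lists were lower in both floxed libraries. Median log2 differences were -0.29 and -0.10 for 30 interferon-response genes and -0.34 and -0.15 for 20 cholesterol genes, and 17 and 13 members were lower in both. Camera gave adjusted p = 0.0015 and 0.0077, and with an estimated correlation adjusted p = 0.823 for each. No member was called, also adjusted over the list alone. The antiviral membrane protein genes Ifitm3 (534 and 977 against 837 CPM) and Ifitm1 (394 and 917 against 720 CPM) were the most abundant interferon-response genes and lay on both sides of the control, while Fdps, a farnesyl diphosphate synthase gene (32.4 and 40.4 against 44.2 CPM), and Srebf2, a regulator of sterol synthesis (31.8 and 40.8 against 43.4 CPM), were lower in both libraries without passing.

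The unfolded protein and heat shock lists passed camera as higher (adjusted p = 0.0023 and 0.0058, and adjusted p = 0.823 for both with an estimated correlation), with 0 called members of 18 and 12, also adjusted over the list alone. In the progenitor clusters the heat shock list passed (adjusted p = 0.028) and the unfolded protein list did not (0.43). Floxed library 1 set the unfolded protein median, 0.44, against -0.00063 in floxed library 2, with the chaperone gene Hsp90b1 at 267, 130 and 151 CPM and Calr at 478, 436 and 437. The heat shock medians were 0.33 and 0.07, and the abundant heat shock genes Hsp90ab1 (2300, 2405 and 2340 CPM) and Hspa8 (1845, 1757 and 1688 CPM) lay close together in all 3 libraries. The 6 sex-linked genes, 4 higher and 2 lower, formed the remaining list past camera (adjusted p = 1.8e-50, and adjusted p = 0.823 with an estimated correlation), and all 6 passed adjusted over the list alone.

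Of the 37 lists 17 passed camera with the preset correlation and none with an estimated correlation or by fry in either form. As the sex-linked list did not pass the latter either, they cannot decide between the lists. The results with the preset correlation are thereby left unchecked. Targets of p53, the tumour suppressor reported to respond to loss of casein kinase 1 alpha, had medians of -0.04 and -0.10 over 26 genes (adjusted p = 0.96), with Rps27l at 635 and 814 CPM against 781 and Bax at 125 and 143 against 144. Targets of beta-catenin (10 tested, adjusted p = 0.17) had medians of 0.32 and -0.10, with Myc at 76.5 and 109 CPM against 95.7 and Jun at 589 and 359 against 324. Neither list had a called member, also adjusted over the list alone. Cytosolic ribosomal protein genes had medians of -0.34 and -0.03 (adjusted p = 0.13), and 2 of its 81 tested members, Rpl39l (17.999, 0.131 and 0 CPM) and Rpl10l (6.12, 0.131 and 0.152 CPM), rose on floxed library 1. With equal cluster shares in every library that list passed as lower (adjusted p = 2.1e-07 by camera). The HSC signature (25 genes, medians -0.08 and -0.10, adjusted p = 0.15) and the mouse counterparts of genes on human chromosome arm 5q (27 genes, medians 0.14 and -0.02, adjusted p = 0.48) did not pass. For apoptosis regulators, where Bcl2a1b was called (10.7, 3.71 and 2.34 CPM), and for genes of quiescence the sign of the median differed from that of camera.

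By size alone 112 of 12156 genes with at least 50 counts differed from the control in both floxed libraries by at least 1.5-fold and beyond the gap between them, 41 higher and 71 lower. The Y-linked genes Uty and Kdm5d were at least 92.9-fold and at least 97.9-fold higher, and Gm16867 at least 11.9-fold. 1700112E06Rik (8.62 and 15.9 against 2.25 CPM) and Gm21967 (8.08 and 6.75 against 2.004) were called higher, while Spaca1 (2.32 and 3.12 against 0.638, adjusted p = 0.13) and C430042M11Rik (1.52 and 1.55 against 0.334, adjusted p = 0.62) did not pass in edgeR. The HoxC cluster genes Hoxc10 (0.0447 and 0.0218 against 3.49 CPM) and Hoxc8 (0.179 and 0.0218 against 1.46 CPM) fell in both libraries. Also lower were 1010001B22Rik (0 and 0.0655 against 3.52 CPM), Gkn3 (0.134 and 0.131 against 2.79), Gm15446 (0.447 and 0.655 against 3.22) and Wfdc2 (0.670 and 0.961 against 3.80), and on the X chromosome Tsix (1.03 and 2.03 against 12.5), Xlr (0.134 and 0.218 against 2.31) and Mid1 (5.49 and 1.94 against 17.3). Taking floxed library 1 as the lone library gave 749 such genes and floxed library 2 gave 180. A 2-fold limit left 28 genes and a minimum of 200 counts 58.

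In HSC-like cells the metallothionein genes fell and the stress-inducible transcription factor gene Klf6 rose. Mt2 was at 0 and 4.31 CPM in the floxed libraries and 62.7 in the control (log2 fold change -4.40, SE 0.45, edgeR adjusted p = 4.4e-19), and Mt1 at 41.6 and 66.7 against 219 (-1.96, SE 0.28, adjusted p = 2.2e-09). Klf6 stood at 376 CPM in floxed library 1, 129 in floxed library 2 and 60.1 in the control (adjusted p = 9.9e-08). Eif2s3y, Ddx3y and Xist differed as in all cells, at least 38.8-fold and at least 34.9-fold higher for the Y-linked genes. In all 14 of 9390 genes were called in HSC-like cells, 8 higher and 6 lower, 5 of them on X or Y, where DESeq2 called 4. Keeping doublets gave 22 calls.

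Lymphoid-like and granulocyte-monocyte-like cells carried the same sex-chromosome differences, and Ly6d, S100a8, Slpi and Ms4a3 rose with their highest level in floxed library 1. In lymphoid-like cells Ly6d rose (257, 36.2 and 23.4 CPM, log2 fold change 2.63, edgeR adjusted p = 3.1e-11), and the haemoglobin gene Hbb-bt (14.1, 15.4 and 43.2 CPM) and the protease gene Klk8 (57.3, 29.9 and 103 CPM) fell. The Y-linked genes Eif2s3y and Ddx3y were at least 55.4-fold and at least 47.3-fold higher there, and Xist had no counts in either floxed library. In granulocyte-monocyte-like cells the neutrophil gene S100a8 (461, 7.02 and 6.998 CPM), the protease inhibitor gene Slpi (107, 25.1 and 19.6 CPM) and Ms4a3 (103, 36.7 and 23.4 CPM) rose, and Eif2s3y and Ddx3y were at least 80.6-fold and at least 72.2-fold higher, with Xist at 0.298 and 1.88 against 4186 CPM. This class was nearly all cluster 1 in floxed library 1 and was shared between clusters 1 and 8 in the other libraries. Lymphoid-like cells had 22 calls of 10263 genes (12 higher, 10 lower, 7 on X or Y) and granulocyte-monocyte-like cells 23 of 10902 (19 higher, 4 lower, 7 on X or Y). DESeq2 called 3 in each, and in granulocyte-monocyte-like cells resolution 1.5 gave 15 calls and turned the S100a8 value to -0.09, and keeping doublets gave 10.

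In dendritic-like cells Nkg7, a cytotoxic granule gene, rose and stood at 26.9 and 96.7 CPM in the floxed libraries and 4.89 in the control (log2 fold change 3.59, edgeR adjusted p = 2.3e-06). Serpinb1a, an inhibitor of neutrophil proteases (15.0, 42.9 and 3.66 CPM), and the lysosomal membrane gene Cd63 (21.4, 51.7 and 4.89 CPM) rose too. Eif2s3y and Ddx3y were at least 11.1-fold and at least 9.70-fold higher, and Xist had no counts in the floxed libraries against 1329 CPM. 15 of 6406 genes were called, 13 higher and 2 lower, 3 of them on X or Y. DESeq2 called 1, and keeping doublets gave 6.

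HSC-like cells took a smaller share of both floxed libraries than of the control. They made up 5.66% of kept cells in floxed library 1 (binomial interval 4.84 to 6.57), 7.14% in floxed library 2 (6.60 to 7.70) and 10.0% in the control (9.23 to 10.8). The floxed mean was 6.3997% ± 1.04 (SD, n = 2), a difference of -3.60 percentage points with an exact permutation p = 0.333, the smallest that 3 libraries allow. This difference hung on how the class was drawn. It was -10.2 points with doublets kept, at resolution 1.5 floxed library 2 lay at the level of the control (8.56% and 16.01% against 16.04%), and with cells of at least 1000 UMIs floxed library 2 was no longer below the control (17.1% and 28.3% against 28.1%). At resolution 0.5, a setting fixed beforehand, the difference was -0.72 percentage points. The class there took in cluster 0, which met the naming rule with 3 HSC markers in its top 25 genes. The top 10 genes of cluster 0 held no HSC marker but held Cxcl12, a stromal marker. Cluster 0 held 28.7% and 29.2% of the floxed libraries against 24.6% of the control. Cluster 4, with 3 HSC markers in its top 10, held 7.41% and 7.35% against 12.4%. Lymphoid-like cells held 10.5%, 8.66% and 11.9% (exact permutation p = 0.667), and granulocyte-monocyte-like cells 11.6%, 19.9% and 16.4%, on both sides of the control. Dendritic-like (5.42%, 1.74% and 2.66%), T-NK-ILC-like (1.96%, 0.209% and 0.284%) and neutrophil-like cells (1.36%, 0.139% and 0.409%) were above the control in floxed library 1 and below it in floxed library 2. The unnamed cluster 9, led by the immediate-early genes Klf6, Fosb, Fos and Jun, held 22.7% of floxed library 1, 0.442% of floxed library 2 and 1.21% of the control, and cluster 13, led by Jchain, Slpi and Mzb1, held 2.94%, 0.151% and 0.107%. A cell sort and the calling of cells set all of these shares, and no class passed in edgeR on cells per class (HSC-like adjusted p = 0.937, 14 classes and clusters tested).

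**Figure D3:**
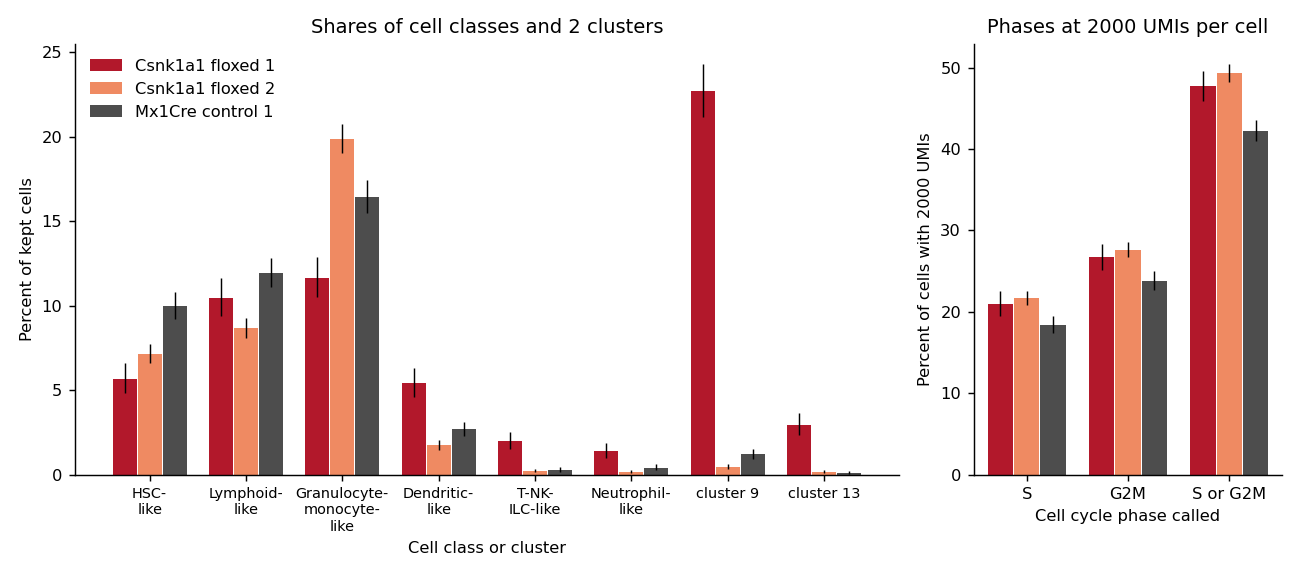
Left, percent of kept cells in the named classes and in clusters 9 and 13 for each library, and right, percent of cells called in S, G2M or either phase after thinning to 2000 UMIs, all with 95% exact binomial intervals that cover counting error only. HSC-like cells stand at 5.66% and 7.14% in the floxed libraries and 10.0% in the control, cluster 9 at 22.7% in floxed library 1, and S or G2M at 47.7% and 49.3% against 42.2%.

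More cells of both floxed libraries were called in S or G2M phase. At 2000 UMIs per cell these phases took 47.7% and 49.3% of cells in the floxed libraries, a mean of 48.5% ± 1.13 (SD, n = 2), and 42.2% in the control, a difference of 6.27 percentage points at the smallest possible exact permutation p = 0.333. S phase stood at 21.0% and 21.7% against 18.4%, and G2M at 26.7% and 27.6% against 23.8%. Without thinning the difference was 6.75 percentage points. HSC-like cells stood at 5.56% and 5.68% in these phases against 5.54%, and there the sign of the difference turned with depth, at 1.22 percentage points with 1000 UMIs per cell and -1.45 without thinning. At 2000 UMIs per cell granulocyte-monocyte-like cells stood at 95.5% and 81.2% against 79.8%, and lymphoid-like cells at 58.9% and 42.8% against 38.3%. Within these classes floxed library 2 lay closer to the control than floxed library 1 did. Whether the mix of classes sets the difference over all kept cells was not tested. At the same depth the median number of genes per cell was 880 and 848 in the floxed libraries and 831 in the control (exact permutation p = 0.667).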

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

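For the calls set by floxed library 1, the tests of free RNA and of the genotype were chosen after the result was seen, and the test of the clusters was fixed before. The rule for mature clusters, on which that last test rests, was written after the cluster tables were seen. Jchain stood out in barcodes that no comparison used, those with at most 50 UMIs. It was at 767 CPM of all UMIs in such barcodes of floxed library 1, against 53.9 in floxed library 2 and 44.1 in the control. In kept cells it was at 2307, 27.7 and 4.42 CPM, and in the progenitor clusters at 19.0, 6.95 and 4.64.

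The 47 calls in which floxed library 1 stood apart from the other libraries were all higher there. Free RNA in the solution is argued against as their source, since all 47 genes lay, in kept cells of that library, at over 3 times the level free RNA could give (17.4 times for the lowest), by the share of 0.113% that the red cell gene Hba-a1 allows. That test was run on Jchain alone before it was widened to the 47 genes. At so small a share the bar is low, and the part of all tested genes that clears it was not counted. The count of 47 therefore adds little to the share itself. Mature cells sorted with the LSK cells are a candidate source, although the sort on lineage markers, Kit and Sca1 would remove such cells. A mature cluster held the highest level within floxed library 1 for 91.5% of the 47 genes, against 45.1% of all tested genes. For 28 it was cluster 13, an unnamed cluster led by Jchain, Slpi and Mzb1, for 8 cluster 15 and for 5 cluster 11. Top genes of cluster 13 also included Xbp1, Tnfrsf17 and Sdc1, and Ly6c2, Ly6d, Cd79a, Prg2 and Cxcl12 from different lists. The calls therefore do not by themselves show a rise of many separate mature cell types. Ly6c2, Ly6d, Cd79a, Prg2 and Cxcl12 are also markers by which cluster 13 was set apart as mature, and they are among the 47 genes. The share of 91.5% is thus partly built in and adds little as a test. Of the 47 genes 9 were still called in the progenitor clusters and 15 were not tested there. Whether the genotype brings more mature cells cannot be told apart from a difference of this library, as floxed library 2 held 4.37% of mature cells and the only control 6.20%.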

How the results depend on the processing

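Progenitor clusters only, genes outside X and Y only, their combination and the robust fit were chosen after the result was seen. Beside the 72 calls in all kept cells, other settings gave 13 with library totals, 10 with DESeq2, 20 with limma-voom, 10 without a low-count filter, 19 at 20 CPM or more, 31 at 1000 UMIs or more, 10 at a 5% mitochondrial limit, 38 with equal cluster shares, 40 in progenitor clusters, 30 there outside X and Y, and 23 with the robust fit. Of these, 19 of the limma-voom calls, 14 at 20 CPM, 33 with equal shares, 33 in progenitor clusters and 24 there outside X and Y were among the 72, and all in the other settings. The stricter filter tested fewer genes (4567), and for the others the cause was not tested. The remaining settings gave 61 to 74 calls. Csnk1a1 stayed lower and uncalled under all 17 settings with a test, at log2 fold changes of -0.46 to -0.37, and at -0.48 and -0.43 without floxed library 1 or 2. Left with floxed library 2 alone, 9 called genes of the set fixed by the naming rule turned, where floxed library 1 alone kept them higher: Cd79a (-0.0770 to 3.18), Cxcl12 (-0.15 to 3.07), Rpl10l (-0.0469 to 3.34), Fcnb (-0.16 to 4.34), Cebpe (-0.57 to 2.35), Elane (-0.60 to 2.29), Ly6c2 (-0.15 to 3.76), Chil3 (-1.14 to 3.04) and Camp (-0.67 to 2.76). Cxcl12 was also at -0.71 in progenitor clusters, with and without X and Y. List medians turned likewise for T and NK (-0.0366 to 1.197), dendritic (-0.20 to 0.81), lymphoid (-0.19 to 0.35), unfolded protein (-0.00063 to 0.44), neutrophil (-1.14 to 1.83) and B cell genes (-0.28 to 0.52), and the neutrophil list passed as lower with equal cluster shares (adjusted p = 4.3e-07). Beside the 17 lists past camera, 0 passed with an estimated correlation, 0 by fry in a single direction and 0 in either direction, while 17, 17, 12 and 18 lists passed with median-of-ratios scaling, equal cluster shares, progenitor clusters and genes outside X and Y, of which 17, 15, 10 and 16 were among the 17. Outside the 17, the erythroid list and the interferon gamma and antigen presentation list (adjusted p = 0.00028 by camera, medians -0.19 and -0.28) passed as lower in progenitor clusters. With equal cluster shares the cytosolic ribosomal protein list passed as lower and the mitochondrially encoded list as higher (adjusted p = 0.0022 by camera). Per class, DESeq2 called 1 dendritic-like, 3 granulocyte-monocyte-like, 4 HSC-like and 3 lymphoid-like genes. Keeping doublets gave 6, 10 and 22 in the dendritic-like, granulocyte-monocyte-like and HSC-like classes, resolution 1.5 gave 15 in granulocyte-monocyte-like cells with S100a8 at -0.0947, and the cause was not tested. Resolution 0.5 gave 34 in a HSC-like class that took in cluster 0, whose top 10 genes held markers of another class, so this count is not that of the same class. The 112 genes by size became 28 at 2-fold and 58 at 200 counts, where the rule itself is stricter. The granulocyte-monocyte-like share difference turned to 1.69 percentage points at resolution 0.5 and 0.332 at 1000 UMIs or more. Without 1 floxed library it ranged from -4.78 to 3.46, and the dendritic-like difference from -0.92 to 2.75, the neutrophil-like from -0.27 to 0.95 and the T-NK-ILC-like from -0.0750 to 1.67. The HSC-like share difference of -3.60 reached -10.2 with doublets kept and was -0.72 for the whole class at resolution 0.5. In cluster 4 there, the HSC-like cluster without a leading marker of another class, it was -5.04. That choice of cluster was made after the result was seen. At 1000 UMIs floxed library 2 was not below the control. S or G2M shares in all kept cells stayed higher in both floxed libraries. A 2-fold change was rarely called at this size of study (3.67% in simulation).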

Other observations

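The tests of mixed sexes, of the genotype, of linked strain DNA and of other groupings of the libraries were chosen after the result was seen, and those of the X-linked genes and of equal cluster shares were fixed before. Barcodes with at most 50 UMIs were rich in myelin and globin RNA that was scarce in kept cells. Mbp, the gene of myelin basic protein, was at 6544, 5021 and 8552 CPM of all UMIs in such barcodes of floxed library 1, floxed library 2 and the control and at 18.7, 18.6 and 19.3 in kept cells, and the globin gene Hba-a1 at 8478, 7005 and 10459 against 9.58, 22.5 and 12.4. These barcodes held 4.73%, 4.37% and 3.62% of each library's UMIs.

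Nnt, a mitochondrial transhydrogenase gene that is disrupted in the C57BL/6J substrain, was at 14.7 and 13.5 CPM in the floxed libraries and 27.5 in the control (edgeR adjusted p = 0.12). Platr27 (1.61, 17.1 and 1.46 CPM), Platr17 (0.268, 15.7 and 1.76 CPM) and Pitx1 (0.268, 3.9955 and 0.0304 CPM) were called on floxed library 2. These genes were chosen after their values were seen.

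The called X and Y genes other than Cybb set the control apart from both floxed libraries. Cybb, on X, was highest in floxed library 1 (14.9, 0.873 and 2.16 CPM). Cells of both sexes within a library are argued against, since Xist in the higher floxed library was at 0.0441% of its control level and 4 Y-linked genes had 0 UMIs in the control against 2407 and 3793. Erdr1 was left out of that count after its 4183 control UMIs were seen, because it lies in the part that X and Y share. The control may come from mice of another sex than the floxed libraries, since Kdm6a, Eif2s3x, Kdm5c and Ddx3x, which escape X inactivation, were lower in both floxed libraries, all 4 of 4, where 25.7% of tested genes were. With 0 floxed libraries carrying the X and Y genes of the control, an effect of the genotype cannot be told apart from sex, for these genes or for any other difference between floxed and control libraries reported here, Csnk1a1, the lists, the classes, the shares and the phases included.

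In the progenitor clusters 13 autosomal calls were shared by both floxed libraries beyond their own gap, 4 higher (among them 1700112E06Rik, Gm16867 and Spaca1) and 9 lower (among them Hoxc10, Hoxc8, Gkn3, Mt2 and the neighbours 1010001B22Rik and Gm15446 on chromosome 5). A different mix of clusters is argued against, since with equal cluster shares their median absolute log2 difference was 94.9% of the value before (1.76 against 1.85). Strain DNA carried along beside the targeted gene is argued against as well, with 0 of the 13 within 20 Mb of Csnk1a1, while strain DNA elsewhere and sex were not tested and stay open. The genotype cannot be told apart from a difference of the lone control library, since 98 genes outside X and Y met the size rule with the control alone, against 484 with floxed library 1 alone and 166 with floxed library 2 alone.

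All 3 splits of the 3 libraries into 2 and 1 called at least as many genes as the 72 of the split by genotype, with 190 for floxed library 2 alone as the highest other, and 3 splits are too few for a share under 0.05.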
